A study of Mus musculus with 24 samples.

How the data were processed

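Total RNA of 24 mouse TS cell cultures was measured on Illumina Mouse-6 bead arrays after amplification with the Illumina TotalPrep kit and labelling with streptavidin-Cy3, per the labels' protocols. The deposited values are intensity per probe on a linear scale, and the submitters' processing notes name BeadStudio without a version. Whether background was subtracted or arrays were normalised before deposit is not given in the sources used here. The first table held 46116 probes on 15 arrays and the second 24044 probes on 9 arrays, and every column had a sample. No deposited intensity lay at or below 0: values ran from 39.8 to 63501 in the first table and from 50.6 to 57327.6 in the second. The log2 medians of the arrays differed by up to 0.582 and 0.176, above the tolerance of 0.1 set for tables taken as already normalised. No 2 columns were identical, and the highest correlation between arrays was 0.996 in the first table and 0.994 in the second.

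Each table was therefore prepared on its own by normexp background correction with an offset of 50, quantile normalization between its arrays and log2 transformation. The offset understates fold changes of dim probes. Folds are those of the fit and can differ slightly from the ratio of the mean intensities. Probes were kept for a fit when they lay above the median of all values of the table (percentile 50) on at least 2 arrays of the fit. Probe annotation gave 1 gene symbol for 29534 probes of the first table and several for 11, and for 21026 and 1 of the second. These covered 17658 and 16031 genes. Of the probes with 1 gene symbol, 99.8% and 99.91% had an Entrez identifier that was in the gene reference. Counts are counts of probes. Where a gene had several probes, the brightest over the arrays of the fit stood for it.

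Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the probes of a fit and a threshold of 0.05. The virus effect, its interaction with the line and the line difference came from the 10 day 3 arrays of the first table with line and virus as terms. The DM, SB and AdGFP against GM contrasts of the first table came from a fit of all 15 arrays with a mean per group. The contrasts of the second table came from an additive fit of all 9 arrays with line, infection, Cre, day 1 and DM as terms, in which the TS15 array is absorbed by its line. The labels call the arrays of the first table's infected cultures biological replicates, so those p-values measure the spread between cultures. In the second table no combination of line, medium, virus and day has over 1 array. Its 2 residual degrees of freedom come from terms left out of the additive fit (line by medium and Cre by day), so its errors and p-values measure departures from that fit, moderated over probes, and not the spread between replicate cultures. Some replicate numbers differ between the titles and descriptions of the labels; those of the titles were used.

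Genes were grouped in 20 lists of 325 genes in all, of which 33 were in neither table. There were 16 lists of pathways or lineages (TS cell self-renewal, FGF and ERK response, trophoblast giant cell, spongiotrophoblast and glycogen cell, labyrinth and syncytiotrophoblast, cell cycle, p53 response and cell cycle inhibitors, matrix proteases and inhibitors, ETS family, interferon and antiviral response, TGF-beta and SMAD response, hypoxia and glycolysis, cholesterol synthesis, steroid hormone synthesis, epithelial keratins and junctions, imprinted genes). The other 4 were of cell types that could be mixed in (embryonic fibroblast, embryonic stem cell or epiblast, primitive or visceral endoderm, macrophage or blood). Lists were tested with camera at a correlation between genes of 0.01, and again with the correlation estimated from the data and with fry. The p-values were adjusted over the lists of a comparison. With an estimated correlation the test has the residual degrees of freedom of the fit, 2 in the second table. It has little power there, so a list that it does not call is left undecided. The genes named are Ets2 in every comparison and the 10 largest rises and 10 largest falls among probes past the threshold with 1 symbol, or the 5 and 5 largest outside the virus effect of the first table, the DM comparisons and the SB comparison. Predicted and clone names were passed over, and for the virus effect only genes with the same sign in both lines were taken. Up to 4 members of each list past the threshold with the largest change were named as well, and any other gene was chosen after its values were seen. The tests, lists, rule for named genes and most alternatives were set before the data were examined; alternatives on array brightness and on a lower offset of 16 were added afterwards.

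The procedure was tested on simulated data drawn from the arrays of each fit. For the virus effect, over 26913 probes, it recovered 97.0% of probes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, and 4.83% of its calls were false. Over 13586 probes of the second table it recovered 4.48%, 44.8% and 84.8% for DM against GM and 0%, 49.3% and 86.4% for the virus effect at those sizes. Only 67, 67 and 66 probes were changed at these sizes, with noise drawn independently for each probe. Where many probes change, as with the 4014 that passed for DM against GM, the adjusted threshold is easier to pass. These shares therefore do not measure recovery or false calls in the real comparisons. Alternatives were no background correction, no normalization between arrays, scaling to a common median, no filter, a filter at percentile 75, no intensity trend, array weights, leaving out each array, and other sets of arrays or terms, whose effect the closing section gives. Versions for tables and plots were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.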

Results

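Transcript levels were measured on Illumina Mouse-6 bead arrays in trophoblast stem (TS) cells, the stem cells of the placenta that are derived from the mouse blastocyst. The 24 arrays came in 2 tables of different probe content, the first with 15 arrays and the second with 9. In the first table, lines TS7 and TS9 had been infected with an adenovirus carrying green fluorescent protein alone (AdGFP, 3 arrays per line) or together with the Cre recombinase (AdCreGFP, 2 arrays per line). RNA of these cultures was taken at day 3 in growth medium. The other 5 arrays of that table included TS7 cells without a named virus in growth medium (GM, 1 array). They also included differentiation medium (DM, without FGF4 and conditioned medium, 2 arrays) and TS7 cells in DM whose titles add SB (2 arrays). The labels give neither the line nor the day of DM replicate 2, nor the meaning of SB. The title of that array names an empty adenovirus, and the description of the other DM array does so as well. The descriptions of the SB arrays read 'Adeno SB'. Whether these 4 cultures were infected, and in what form SB was given, is unclear. The second table held TS9 cultures infected with either virus, with 1 array per virus at day 1 and at day 3, and 1 TS15 AdCreGFP culture at day 3. It also held uninfected TS7 and TS9 cultures, 1 of each in GM and 1 of each in DM. The labels do not give the day of the TS9 culture in GM. The median deposited signal lay between 92.4 and 138.3 on the arrays of the first table and between 114.2 and 129 on those of the second, and the number of arrays limits the precision of every value.

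Ets2, the ETS-domain transcription factor whose floxed gene is the target of Cre in this design, was read by a single probe in each table, and its signal was higher, not lower, on every array labelled AdCreGFP. In the first table the mean intensity was 6816 ± 395 (SD, n = 4) on arrays labelled AdCreGFP, with single arrays from 6413 to 7317. On AdGFP arrays it was 3585 ± 545 (SD, n = 6), from 2743 to 4156. The rise was 0.94 ± 0.10 on the log2 scale (SE), or 1.92-fold, with an adjusted p of 0.000124, and came to 0.95 in TS7 and 0.93 in TS9. In the second table the 3 arrays labelled AdCreGFP gave 8390 ± 1086 (SD), from 7588 to 9625, against 4911 and 4944 on the 2 AdGFP arrays. Cells in GM without virus gave 3504 in the first table (n = 1) and 4335 ± 943 in the second (SD, n = 2). In DM the Ets2 signal was 4949 ± 289 in the first table (SD, n = 2) and 7672 ± 1769 in the second (SD, n = 2). With SB it was 3093 ± 229 (SD, n = 2). The position of the probe relative to the deleted exons is not given, so this signal checks neither the deletion nor the labels. It did not show the loss that the label AdCreGFP stands for.

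**Figure D1:**
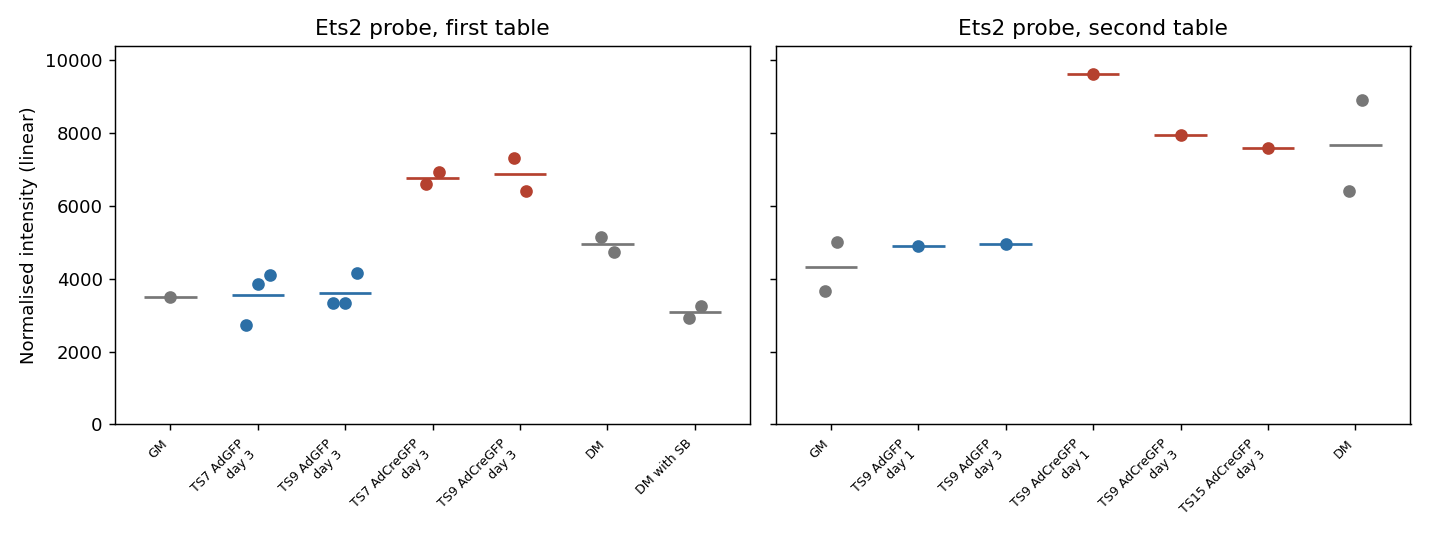
Normalised linear intensity of the Ets2 probe (vertical axis) on each array of the first (left) and the second table (right), by group; points are single arrays, horizontal lines are group means, red marks AdCreGFP, blue AdGFP and grey the other cultures. The arrays labelled AdCreGFP lie between 6413 and 7317 in the first table and between 7588 and 9625 in the second, above every AdGFP array of their table.

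Arrays labelled AdCreGFP were compared with AdGFP arrays at day 3 to ask what changes in TS cells once Cre is delivered to the floxed Ets2 gene. Transcripts of the stem cell state were among the falls. Esrrb, an orphan nuclear receptor needed for TS cell maintenance, went from 8025 ± 860 to 5544 ± 306 (SD, n = 6 AdGFP and 4 AdCreGFP arrays) and fell by 0.53 on the log2 scale (adjusted p = 6.85e-05). Cdx2, the caudal homeobox factor of the trophectoderm, fell by 0.55 from 2033 ± 209 to 1406 ± 308 (adjusted p = 0.00397). Sox2 fell by 0.54 from 527.2 ± 57.9 to 363.9 ± 60.2 (adjusted p = 0.00289). Of the 12 measured self-renewal genes 4 fell and none rose, with Bmp4 as the fourth (-0.36), and 8 fell when adjusted over the list alone. Their median change was -0.19 (camera adjusted p = 1.06e-05), a call that held with an estimated correlation (adjusted p = 0.0267). Without normalization, or with median scaling, this median was -0.10. Of the targets of FGF and ERK signalling, the pathway that FGF4 drives in these cells, 5 of 15 measured members fell and none rose, 5 also when adjusted over the list alone. The median was -0.10 (camera adjusted p = 0.00272), a call that was lost with an estimated correlation (adjusted p = 0.21). By line, the median of this list was -0.24 in TS7 and -0.04 in TS9. Spry4, a feedback inhibitor of the pathway, changed by -0.61, the ETS factors Etv5 and Etv4 by -0.50 and -0.40, and Myc by -0.36.

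The largest rises among named genes were of Pmp22, a myelin and junction protein (log2 change 1.25 ± 0.08 SE, from 477.5 ± 126 to 1173 ± 458, adjusted p = 1.46e-06), and of the monocyte chemokines Ccl2 and Ccl7. Ccl2 went from 164.8 ± 24.1 to 362.8 ± 18.2 (1.15 ± 0.10, adjusted p = 1.93e-05), Ccl7 changed by 1.15 ± 0.08 and the betaine transporter Slc6a12 by 1.10. Spsb1 (1.03) and the transglutaminase Tgm2 (0.97) followed, then Ets2 itself (0.94), the basal keratin Krt14 (0.89), the small heat shock protein Cryab (0.87) and the macrophage growth factor Csf1 (0.81). The largest falls were of Ctsj, a placental cathepsin (log2 change -1.11 ± 0.07 SE, from 425.8 ± 114 to 198.3 ± 59.3, adjusted p = 5.04e-07), and of Socs2, an inhibitor of cytokine signalling (-1.07 ± 0.11, from 1084 ± 32.4 to 532 ± 142). The proprotein convertase Pcsk6 fell 2.01-fold, from 1738 ± 148 to 864.4 ± 45.6, and further falls were of Ccdc3 (-1.06), Robo4 (-0.99), Ly6c1 (-0.85), the pyruvate dehydrogenase kinase Pdk1 (-0.84) and Trim9 (-0.84). Prl2c3 (-0.86) and Prl2c4 (-0.75) were also among the falls. They and Prl2c2 (-0.75) are nearly identical prolactin family genes, so which of them fell is uncertain. Errors of levels are SD with n = 4 for AdCreGFP and n = 6 for AdGFP.

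Cell cycle genes fell in 5 of 21 measured members, among them Cdc20 (-0.34), Mki67 (-0.28), Mcm6 (-0.28) and Mcm3 (-0.27), and none rose. With only the list's own probes adjusted, 12 fell. The median was -0.19 (camera adjusted p = 3.82e-06), but adjusted p = 0.15 with an estimated correlation, and it was -0.10 without normalization or with median scaling. By line, the median of the cell cycle genes was -0.06 in TS7 and -0.29 in TS9. Cdkn2b, an inhibitor of the G1 kinases, rose (0.52, adjusted p = 0.000335), as did Mdm2, the p53 ligase (0.17, adjusted p = 0.0465). The list of p53 targets and inhibitors as a whole, with 2 of 15 up, was not called (camera adjusted p = 0.442). Epithelial keratins and junction genes rose in 5 of 11 members and in 6 when adjusted over the list alone. The largest of these rises were of Krt7 (0.57, from 11712 ± 1951 to 17359 ± 2753, SD), Krt18 (0.37), Cldn4 (0.35) and Krt8 (0.32). This was the other call that held with an estimated correlation (camera adjusted p = 0.000352, adjusted p = 0.0449 with an estimated correlation), with a median of 0.17 that was 0.27 without normalization or with median scaling. Interferon-induced genes rose in 4 of 13 members (Isg15 0.73, Usp18 0.71, Rsad2 0.42, Mx2 0.27) and in 5 when adjusted over the list alone. The median was 0.09 (camera adjusted p = 0.000368, adjusted p = 0.0888 with an estimated correlation). Of the 13 measured matrix genes, the protease inhibitors Timp1 (0.70) and Timp3 (0.49), the membrane protease Mmp14 (0.63) and the urokinase receptor Plaur (0.41) rose and 1 gene fell. Adjusted over the list alone 5 rose and 2 fell. The median was 0.06 (camera adjusted p = 0.0494, adjusted p = 0.256 with an estimated correlation).

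TGF-beta and SMAD targets rose in 3 of 13 members, Ccn2 (0.78), Ltbp2 (0.56) and Id1 (0.27), and Smad6 fell (-0.27). Within the list alone 5 rose and 1 fell. The median was 0.10 (camera adjusted p = 0.0106, adjusted p = 0.166 with an estimated correlation). For Ltbp2, 1 of 3 probes passed in the opposite direction. Genes of hypoxia and glycolysis fell in 4 of 13 members, Pdk1 and the glucose transporter Slc2a3 (-0.67) with the glycolytic enzymes Pfkl (-0.25) and Aldoa (-0.22). With only the list's own probes adjusted, 2 rose and 4 fell. The median was -0.10 (camera adjusted p = 0.00591, adjusted p = 0.0888 with an estimated correlation), and -0.05 without normalization or with median scaling. Cholesterol synthesis had 1 fall among 12 members, Dhcr7 (-0.42), and 8 when adjusted over the list alone (camera adjusted p = 0.000352, adjusted p = 0.166 with an estimated correlation), with a median of -0.18 that was -0.09 without normalization or with median scaling.

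Lists of the differentiated placental lineages were not called in this comparison. Of 12 giant cell genes 2 fell, Ctsj and Prl2c2, none rose, and 1 rose when adjusted over the list alone (camera adjusted p = 0.914; the median was 0.07 while the mean and the test pointed down). Of 9 spongiotrophoblast and glycogen cell genes Pcdh12 fell (-0.36; camera adjusted p = 0.981), and none rose. Of 12 labyrinth genes Cebpb, a factor of the labyrinth, rose (0.46) and Ly6e, the receptor for syncytin-A, fell (-0.33; camera adjusted p = 0.914). In the ETS family list 1 of 16 members passed, Ets2 (camera adjusted p = 0.914). The ETS factors Etv4 and Etv5, which fell, stand in the FGF and ERK list and are not counted there. In steroid hormone synthesis none of 7 passed (camera adjusted p = 0.319). Among imprinted genes Grb10 fell (-0.32), 1 of 13 (camera adjusted p = 0.914). Markers of cells that could be mixed into the cultures gave camera adjusted p = 0.914 in each of 4 lists. None of 11 embryonic fibroblast and none of 5 macrophage or blood genes passed. Klf2 rose (0.50) while Utf1 (-0.42) and Dppa4 (-0.29) fell among 7 embryonic stem cell or epiblast genes. Gata6 rose (0.29) while Amn fell (-0.29) among 8 endoderm genes.

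By limma, 1217 of 26913 probes passed an adjusted p of 0.05 between arrays labelled AdCreGFP and AdGFP, 620 higher and 597 lower. Of them 16 differed by over 2-fold. Among these 16 are probes without a gene name that read on arrays labelled AdCreGFP only, such as 104590471 and 104920152. What such probes read is not given. The median absolute log2 change of the probes that passed was 0.32. Without normalization between the arrays the count was 640, of which 73% were higher, and without the line in the model it was 172. Leaving out single arrays moved the count by over 1.5 times in 6 cases. It was 662 and 754 without TS9 AdCreGFP replicates 1 and 3, and 762 and 765 without TS9 AdGFP replicates 2 and 3. It was 747 without TS7 AdGFP replicate 2 and 800 without TS7 AdCreGFP replicate 2.

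**Figure D2:**
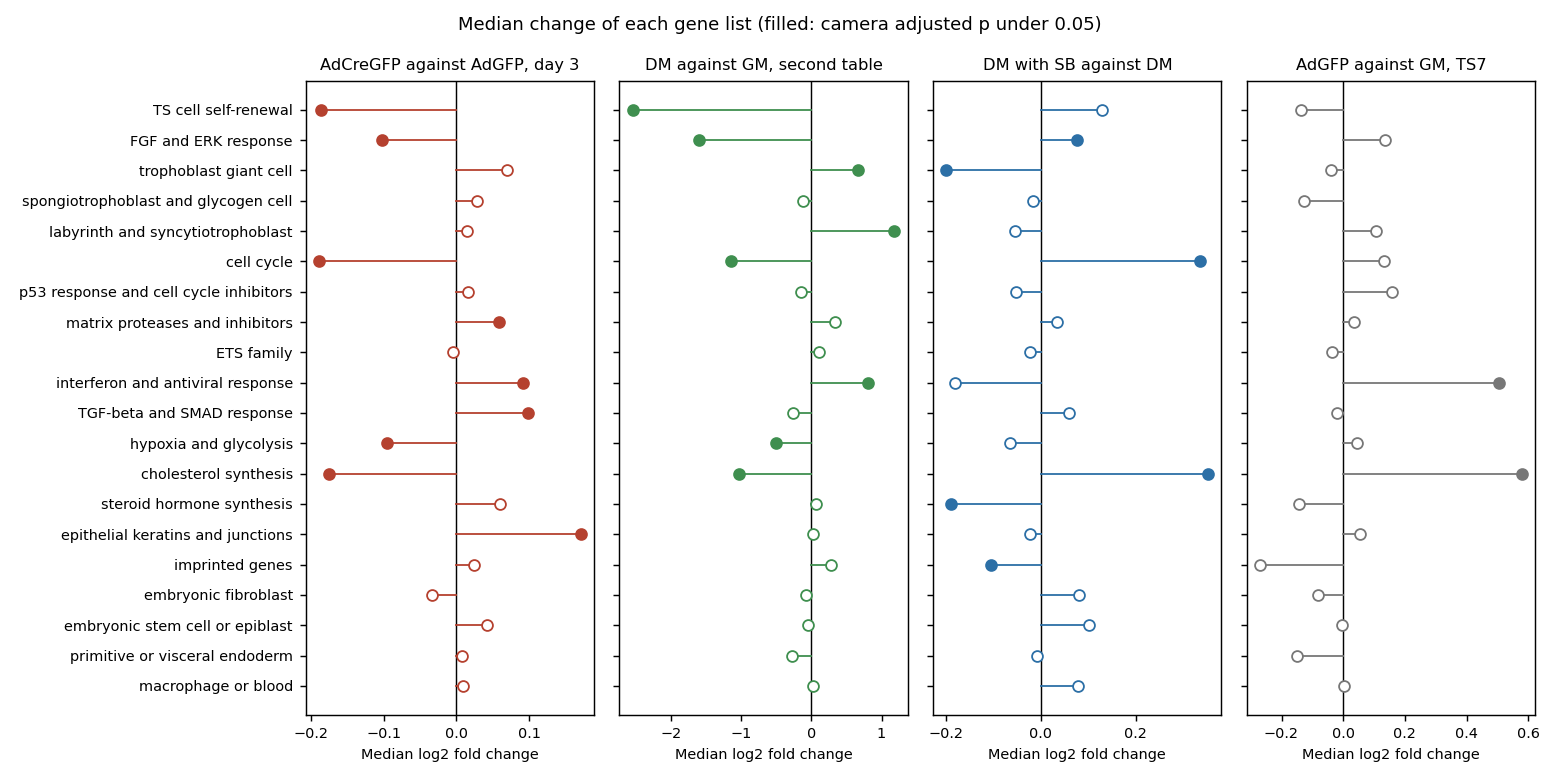
Median log2 fold change (horizontal axes, each on its own scale) of the measured members of the 20 gene lists in 4 comparisons; points are list medians, joined to 0 by a line, and are filled where the camera adjusted p was under 0.05. Self-renewal genes lie at -0.19 on arrays labelled AdCreGFP and at -2.55 in DM, and interferon genes at 0.50 in AdGFP against GM.

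The effect of the virus differed between the lines for a small set of transcripts. Dusp4, a phosphatase that turns off ERK, was lower on TS7 arrays labelled AdCreGFP (585.1 ± 9.79, SD, n = 2) than on TS7 AdGFP arrays (884.4 ± 8.23, n = 3). In TS9 it was higher (815.4 ± 27.2, n = 2, against 594 ± 46.8, n = 3), and it passed within each line. The smooth muscle actin Acta2 fell by 0.45 in TS7 and rose by 0.54 in TS9 on the log2 scale. Chac1, a glutathione-degrading enzyme of the stress response, fell by 1.11 in TS7 (from 289.5 to 134.4) against a change of 0.15 in TS9. Its TS9 AdGFP level was already low, at 142, so a like fall could hardly show there. Txnip, an inhibitor of thioredoxin, rose by 1.34 in TS7 (from 896.1 to 2257) against 0.20 in TS9, where the AdGFP level was already 2378. Spsb1 rose in both, by 0.62 in TS7 and 1.45 in TS9. The other 5 of the 10 probes that passed the test of the difference (7 higher in TS9, 3 lower) carry no gene name. Of these, probes 104590471 and 104920152 read on no day 3 array but those labelled AdCreGFP, and lower in TS9 (1542 ± 64.3 and 2246 ± 32.2, SD, n = 2) than in TS7 (2965 ± 158 and 4227 ± 232, n = 2). Among the lists, that of 21 cell cycle genes had a median difference of -0.17, lower in TS9 than in TS7 though not for every member (camera adjusted p = 1.93e-06, adjusted p = 0.0265 with an estimated correlation). None passed singly, and 6 did when adjusted over the list alone. The FGF and ERK targets, with Dusp4 as 1 of 15 past the threshold, had a median difference of 0.19 (camera adjusted p = 0.000364, adjusted p = 0.0768 with an estimated correlation). It turned to -0.01 without normalization between the arrays, where that of the cell cycle genes was -0.41. Cholesterol synthesis, with none of 12 past the threshold, had a median of -0.14 (camera adjusted p = 0.0292, adjusted p = 0.37 with an estimated correlation), and -0.38 without normalization. The other 17 lists were not called. The count of 10 rests on single arrays. It was 0 without TS9 AdCreGFP replicate 3, and 1 without TS9 AdCreGFP replicate 1, TS7 AdGFP replicate 2 and TS7 AdCreGFP replicate 1, each left out alone. It was 2 without TS9 AdGFP replicate 2, 3 without TS9 AdGFP replicate 3 or TS7 AdCreGFP replicate 2, and 5 without TS9 AdGFP replicate 4. With array weights it was 36 and without normalization 4, most of which were lower in TS9. In both lines the Ets2 signal was higher on the arrays labelled AdCreGFP, which checks neither the deletion nor the labels.

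**Figure D3:**
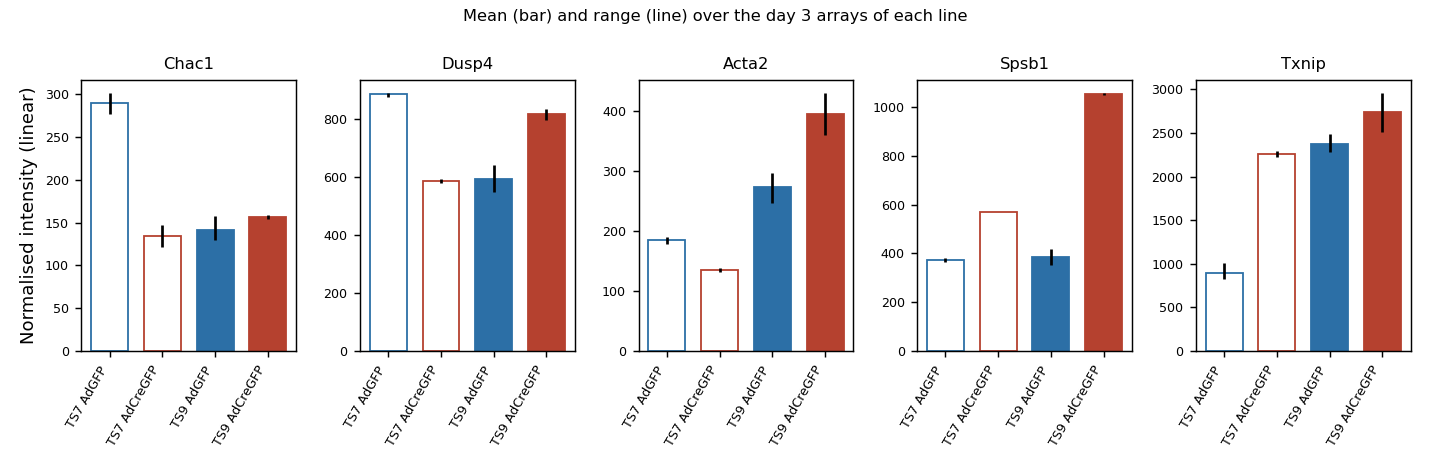
Normalised linear intensity (vertical axes, from 0) of 5 genes whose response to the virus differed between lines, in TS7 (open bars) and TS9 (filled bars), each with 3 AdGFP and 2 AdCreGFP arrays; bars are means and black lines run from the lowest to the highest array. Dusp4 goes from 884.4 to 585.1 in TS7 and from 594 to 815.4 in TS9.

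The lines themselves differed at many transcripts over both viruses. TS9 arrays had more Mgmt, the enzyme that repairs alkylated guanine (942.6 ± 55 against 108.7 ± 5.01, SD, n = 5 each, log2 difference 3.12, adjusted p = 2.09e-13) and more Nbdy (3.01). They also had more signal from the Prl2c2, Prl2c3 and Prl2c4 probes (3.09, 3.07 and 3.07), and which of these near-identical genes differed is uncertain. They had less Ipp (-3.14), Jpt1 (-2.98), Xist, the RNA that silences an X chromosome (-2.37), Nup62cl (-2.31) and Laptm5 (-1.96). Mgmt and Nbdy in TS7 (108.7 and 79.1) and Xist in TS9 (85.7) lay near background, so the exact size of these differences is uncertain. Interferon-induced genes were lower in TS9 in 9 of 13 members, such as Isg15 (-1.34, 349.2 ± 112 against 873.1 ± 237), Rsad2 (-1.14), Usp18 (-0.96) and Bst2 (-0.79). Adjusted over the list alone 9 were lower too, and the median was -0.38 (camera adjusted p = 2.7e-07, adjusted p = 0.0645 with an estimated correlation). Cholesterol synthesis enzymes were lower in 10 of 12 members and in all 12 when adjusted over the list alone, among them Cyp51 (-0.78), Fdps (-0.57), Dhcr7 (-0.52) and Sqle (-0.41). Their median was -0.39 (camera adjusted p = 1.4e-08, adjusted p = 0.0952 with an estimated correlation). Cell cycle genes were lower in 7 of 21, with Aurkb (-0.61) and Top2a (-0.60), and higher in 1, Ccne2 (0.47). Within the list alone 10 were lower and 1 higher (camera adjusted p = 0.00577, adjusted p = 0.419 with an estimated correlation), with a median of -0.18 that was -0.31 without normalization. Keratins and junction genes were higher in 4 of 11, with Cldn4 (0.55) and Krt7 (0.40), and lower in 1. With only the list's own probes adjusted, 6 were higher and 2 lower (camera adjusted p = 0.0263, adjusted p = 0.156 with an estimated correlation), with a median of 0.13 that was 0.02 without normalization. Outside the called lists, Eomes (0.67), the urokinase Plau (1.51), Cyp11a1 (1.13) and the imprinted Ndn (1.59) and Mest (1.56) were higher in TS9, and Slc2a3 (-1.47) and Cdkn2b (-0.98) lower. By limma 4797 of 26913 probes passed, 2661 higher and 2136 lower in TS9. The deposited brightness of the arrays also differed between the lines, and within the 5 dimmer and the 5 brighter arrays the counts were 1587 and 699, each from 4 arrays of 1 line against a single array of the other. Without normalization 22% of the probes that passed were higher in TS9, against 55% with it.

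Differentiation of TS cells on withdrawal of FGF4 and conditioned medium was measured as DM against GM, in the second table with 1 TS7 and 1 TS9 array in each medium. Its errors come from departures from an additive fit and not from replicate cultures of a line. Most self-renewal genes fell. Esrrb, whose DM level lay near background so that the exact fold is uncertain, fell 61.5-fold by the fit (log2 change -5.94 ± 0.14 SE, from 7304 ± 293 to 119.8 ± 22.3, SD, n = 2 each, adjusted p = 2.82e-07). Elf5, an ETS factor of the trophoblast lineage, fell from 3714 ± 913 to 155.5 ± 99.6 (-4.72) and Cdx2 from 1945 ± 367 to 147.6 ± 50.3 (-3.75). Eomes, a T-box factor of the trophectoderm, fell by 3.20 on the log2 scale. Of the 12 self-renewal genes 9 fell and none rose. FGF and ERK targets fell in 11 of 15 members, with the ERK phosphatases Dusp6 (-3.63) and Dusp4 (-2.17), the immediate early factor Egr1 (-3.90) and cyclin D1, Ccnd1 (-2.83). Cell cycle genes fell in 15 of 21 and rose in 2, with Cdc20 (-2.57), Plk1 (-2.43), Mki67 (-2.18) and Aurkb (-2.11), while the kinase inhibitor Cdkn1c rose by 2.11. Both DM arrays gave it the same normalised value, 32683.

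The giant cell and labyrinth lists were called as higher in DM by camera, but not with an estimated correlation (adjusted p = 0.441). The spongiotrophoblast and glycogen cell list, with 1 of 6 up and a median of -0.12, was called by neither (camera adjusted p = 0.954). At 2 residual degrees of freedom the test with an estimated correlation has little power, so its misses decide little. Gata2, a factor of giant cells, rose by 2.31 and Ctsj from 352.2 ± 305 to 5372 ± 441 (4.27, SD, n = 2 each). Prl4a1 rose by 2.63 and the Prl2c2 probe by 1.52. Of 10 measured giant cell genes 5 rose and none fell. In the labyrinth list 5 of 7 rose and 1 fell, with the connexin Gjb2 (from 88.8 ± 5.96 to 921.7 ± 255, 3.35), the homeobox factor Dlx3 (2.40), Cebpb (1.51) and the cathepsin Ctsb (1.18). The largest rise was of Myl4, an atrial myosin light chain (25.3-fold, log2 change 4.66 ± 0.17 SE, from 199.8 ± 19.5 to 5067 ± 794, adjusted p = 1.73e-06). Pparg, a nuclear receptor of placental and fat cell differentiation, rose from 128.2 ± 37.9 to 1596 ± 270 (3.66). The GM levels of Gjb2 and Pparg lay near background, so their exact folds are uncertain. Other large rises were of Serpinb9g (3.81), Arhgef6 (3.65), Rsad2 (3.43), Serpinb9e (3.22), Ctsr (3.18) and Lgals9 (2.95). The Serpinb9 and the placental cathepsin genes have close paralogs, so which member rose is uncertain. Falls of similar size were seen for Sox21 (-4.72), Duoxa2 (-4.54), Ccdc3 (-4.31), the gelatinase Mmp9 (-4.22, from 4861 ± 668 to 272.8 ± 117), Pou3f1 (-4.13), Ddah1 (-3.94) and Prss46 (-3.78).

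Interferon-induced genes rose in 10 of 12 members in DM and 1 fell, with Rsad2, Isg15 (2.36), Usp18 (2.36) and Mx2 (1.49). Cholesterol synthesis enzymes fell in 8 of 12, with Msmo1 (-1.65), Mvd (-1.51), Hmgcs1 (-1.37) and Cyp51 (-1.18). Hypoxia and glycolysis genes fell in 9 of 13 and rose in 2, with Slc2a3 (-1.96), Pdk1 (-1.53) and Pfkl (-1.15) down and Ndrg1 (1.80) up. These 8 lists were called by camera, with adjusted p of 2.11e-07 for self-renewal (median -2.55), FGF and ERK response (-1.61) and cell cycle (-1.14). It was 2.78e-05 for cholesterol synthesis (-1.04), 5.43e-05 for interferon (0.81), 0.00183 for labyrinth (1.18), 0.00987 for giant cells (0.67) and 0.043 for hypoxia and glycolysis (-0.51). Each had an adjusted p = 0.441 with an estimated correlation, a test with little power in the second table. Adjusted over the list alone, 12 FGF and ERK genes and 17 cell cycle genes fell, and the other counts did not change. Lists that were not called held rises of the steroid side-chain cleavage enzyme Cyp11a1 (2.11), Hsd17b2 (1.56), Krt19 (2.22), Krt7 (1.03) and the imprinted Phlda2 (2.43) and Peg3 (1.14), and of Ccn2 (1.63), Mmp14 (1.13), and Ascl2 (0.48). The ETS factors Elf1 (1.68) and Elf3 (1.38) also rose, and Smad6 (-2.32) and Mest (-1.14) fell. Ets2 rose by 0.82 ± 0.12 (SE, adjusted p = 0.00135). Among markers of other cell types, Acta2 rose (2.40) and Utf1 (-2.93) and Dppa4 (-1.21) fell. By limma 4014 of 13586 probes passed, 2064 higher and 1950 lower, 1049 of them by over 2-fold. From the 4 medium arrays alone, without the line in the model, 1789 passed and the adjusted p of Ets2 was 0.0586; Prl4a1 had an adjusted p of 0.33 without GM replicate 3 or without DM replicate 4.

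The first table repeated this comparison with 2 DM arrays against 1 GM array, which was assumed to vary like the other groups. The title of 1 of these DM arrays and the description of the other name an empty adenovirus, so an effect of such a virus was not separated from that of the medium. Esrrb fell 63.8-fold by the fit (-5.99 ± 0.11 SE, from 7289 to 114.5 ± 8.96, SD, n = 2, adjusted p = 3.49e-15), with Elf5 (-5.21), Sox21 (-5.01), Mmp9 (-4.42), Cdx2 (-4.24) and Eomes (-3.54). The largest rises were of Myl4 (33.0-fold), Ctsj (31.9-fold), Pparg (14.2-fold), Acta2 (11.9-fold), Tgm2 (10.1-fold) and Igfbp2 (10.05-fold). Levels near background, of Esrrb in DM and of Ctsj and Pparg in GM, make these folds uncertain. Of 29915 probes 7526 passed by limma, 3994 higher and 3532 lower. Falls prevailed in self-renewal (9 of 12, none up, median -2.05), FGF and ERK response (13 of 15, 1 up, -1.68), cell cycle (18 of 22, 2 up, -1.62) and cholesterol synthesis (9 of 12, none up, -0.69). Of 13 interferon genes 10 rose and 1 fell. These 5 lists were called by camera (adjusted p from 2.98e-11 to 4.44e-05). They were also called with an estimated correlation (adjusted p = 0.0022 for self-renewal and for cell cycle, 0.00275 for FGF and ERK, 0.00951 for cholesterol and 0.0398 for interferon). Giant cell (4 of 13 up, adjusted p = 0.0222), labyrinth (6 of 12 up, 1 down, 0.0222), hypoxia (2 up and 7 down of 13, 0.0178), imprinted (7 of 13 up, 1 down, 0.018) and matrix genes (8 of 13 up, 1 down, 0.0222) were called by camera. With an estimated correlation they had adjusted p = 0.0625, or 0.103 for matrix genes. Within the list alone, 3 cell cycle genes and 8 imprinted genes rose, and the other counts of these 10 lists did not change. Ets2 changed by 0.50 ± 0.18 (SE), with an adjusted p of 0.0585. Across 9716 genes measured in both tables the DM changes had a Pearson r of 0.91 and a Spearman rho of 0.83 (across genes, which are not independent replicates). Of 2485 genes that passed in both, 99.8% had the same sign, against 78.7% of all 9716.

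The response to AdCreGFP and the response to DM, measured on different tables with no shared control arrays, moved the same way for most genes. Of 769 genes that passed between the viruses and were measured in both, 700 (91.0%) had the same sign in DM of the second table, and 64.9% of all 9602 genes did. With the labels of the viruses exchanged, 69 of the 769 (8.97%) would have the same sign. Of these 769, 536 passed there as well: 260 were higher and 255 lower in both, where chance gives 63.2 and 55.5, and 10 and 11 went opposite ways. Tgm2, Slc6a12, Krt14, Isg15 and Usp18 rose in both and Esrrb, Cdx2, Sox2, Socs2, Ccdc3 and Pcsk6 fell in both. Ctsj was an exception, with a fall of 1.11 on arrays labelled AdCreGFP and a rise of 4.27 in DM, and so were the Prl2c2 probe (-0.75 and 1.52) and Ltbp2 (0.56 and -0.46). Across 9602 genes the log2 changes had a Pearson r of 0.53 and a Spearman rho of 0.47 (across genes). The 1506 genes that rose in DM had a median of 0.12 on arrays labelled AdCreGFP (camera adjusted p = 2.01e-25, adjusted p = 0.00073 with an estimated correlation). The 1455 that fell in DM had a median of -0.11 (camera adjusted p = 5.19e-25, adjusted p = 9.68e-05 with an estimated correlation). With the DM arrays of the first table r was 0.46. The direction is that of the labels, and the Ets2 signal itself rose on arrays labelled AdCreGFP.

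**Figure D4:**
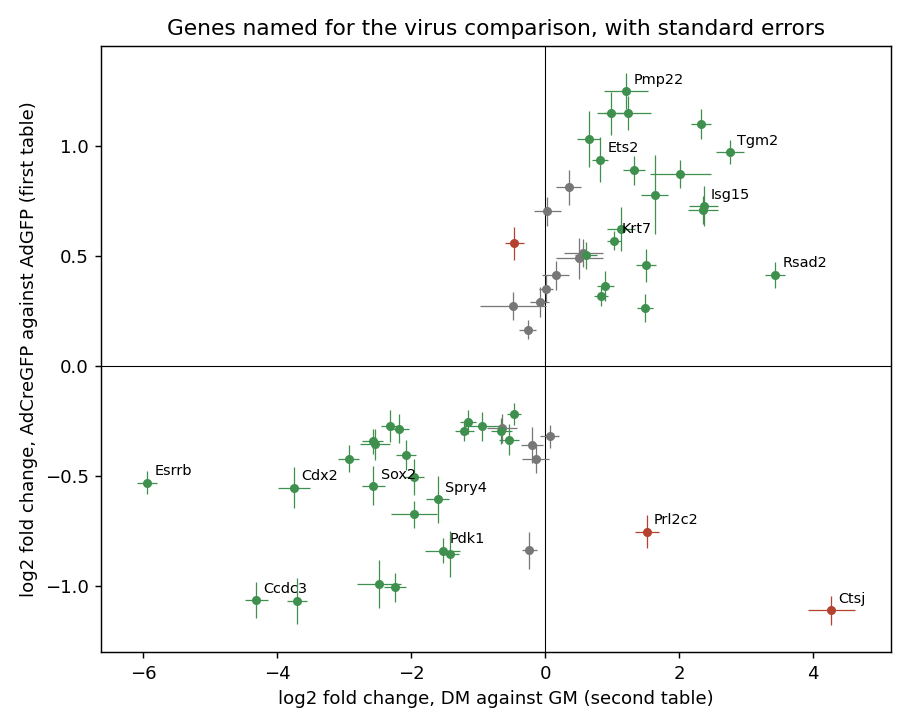
Log2 fold change of the genes named for the virus comparison, in DM against GM (second table, horizontal axis) and in AdCreGFP against AdGFP (first table, vertical axis); points are genes with standard errors, green where past the threshold in DM with the same sign, red with the opposite sign and grey where not past it. Esrrb lies at -5.94 and -0.53, Tgm2 at 2.76 and 0.97, and Ctsj at 4.27 and -1.11.

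DM with SB was compared with DM alone in the first table, where the labels of both groups mention an adenovirus. Tagln (transgelin) rose from 114.1 ± 4.76 to 535.4 ± 21.7 (log2 change 2.23 ± 0.11 SE, SD with n = 2 each, adjusted p = 2.25e-09) and Acta2 from 2875 ± 163 to 12801 ± 651 (2.15). The Tagln level in DM lay near background, so its exact fold is uncertain. The muscle actins Acta1 (1.73) and Actg2 (1.71) and the myosin Myh7 (2.82-fold) rose with Pou3f1 (1.95), Ly6c1 (1.55), Capn6 (1.53) and Ddah1 (1.52). The probes of the near-identical Prl2c3 (-2.57), Prl2c2 (-2.50) and Prl2c4 (-2.44) fell, with the cathepsins Ctsr (-2.10) and Ctsj (from 3990 ± 380 to 1053 ± 2.77, -1.92). Other falls were of Cyp11a1 (from 1366 ± 41.4 to 365.1 ± 14.4, -1.90), Rhox12 (-1.88), Acp7 (-1.69), Mfsd2a (-1.66) and Alpl (-1.63). Ets2 fell by 0.68 (adjusted p = 0.00727).

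Cell cycle genes rose with SB in 11 of 22 members, with Plk1 (1.17), Top2a (1.14), Birc5 (1.10) and Mki67 (0.92), and 1 fell. With only the list's own probes adjusted, 13 rose and 1 fell, and the median was 0.34 (camera adjusted p = 2.51e-08, adjusted p = 0.0121 with an estimated correlation). Cholesterol synthesis rose in 6 of 12 and in 7 when adjusted over the list alone, with Msmo1 (0.91), Cyp51 (0.77), Hmgcs1 (0.72) and Fdps (0.60). It had a median of 0.35 (camera adjusted p = 8.27e-07, adjusted p = 0.0143 with an estimated correlation). Giant cell genes fell in 4 of 13 and 1 rose, and steroid synthesis genes fell in 2 of 7, Cyp11a1 and Hsd17b2 (-0.76). Imprinted genes fell in 5 of 13, with Phlda2 (-1.23), Peg10 (-1.19), Cdkn1c (-0.66) and Grb10 (-0.48). Each of these lists had a camera adjusted p of 0.00668 and an adjusted p = 0.0499 with an estimated correlation. Adjustment within each list gave 6 FGF and ERK genes, 1 giant cell gene and 1 imprinted gene that rose, and 2, 5 and 5 that fell, with 3 falls among steroid genes. FGF and ERK targets rose in 5 of 15, with Ccnd1 (from 397.1 ± 28.9 to 1457 ± 29.9, 1.88), Phlda1 (1.21), Egr1 (1.09) and Spred1 (0.90), and 1 fell. The list was called by camera alone (camera adjusted p = 0.0231, adjusted p = 0.118 with an estimated correlation). Self-renewal genes were not called as a list (camera adjusted p = 0.788): Bmp4 (1.40) and Id2 (0.63) rose and Tead4 (-0.81), Gata3 (-0.62) and 1 other member fell. The protease inhibitors Timp2 (1.28), Timp3 (1.25) and Timp1 (1.19) and the TGF-beta targets Tgfbi (1.30), Ccn1 (1.28) and Ccn2 (1.04) rose in lists that were not called (camera adjusted p = 0.261 and 0.0519). Of the fibroblast markers 3 of 12 rose, Acta2, Thy1 (1.01) and Col1a1 (0.65; camera adjusted p = 0.0858). By limma 2960 of 29915 probes passed, 1490 higher and 1470 lower, while with median scaling most of those that passed were higher. Without single arrays the count was 1926 and 1863 (DM replicates 2 and 1) and 1767 and 1822 (SB replicates 1 and 2).

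The SB changes ran against the DM changes of the second table. Of 932 genes past the threshold in both, 481 were lower with SB and higher in DM and 372 were the reverse, where chance gives 125.7 and 117.1. The same sign was found for 8.48% of the 932, against 36.8% of all 9716 genes. Across 9716 genes the Pearson r was -0.50 and the Spearman rho -0.42. Genes that rose in DM had a median of -0.18 with SB (adjusted p = 0.000819 with an estimated correlation) and those that fell had 0.18 (adjusted p = 5.17e-05 with an estimated correlation). The mean Ets2 signal followed the same order, at 3504 in GM, 4949 in DM and 3093 in DM with SB in the first table.

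In the second table, arrays labelled AdCreGFP were set against AdGFP in TS9 over days 1 and 3, with 2 arrays per virus in the contrast. Ets2 was higher by 0.83 ± 0.12 on those labelled AdCreGFP (SE, unadjusted p = 8.87e-05, adjusted p = 0.305), as in the first table. By limma no probe of 13586 passed, and 590 had an unadjusted p under 0.05, fewer than the 679 that chance gives. The lowest adjusted p was 0.305. Genes of the first table's virus response moved the same way, with the same sign for 732 of 769 (95.2%), against 62.8% of all 9602 genes. The 403 that had risen had a median of 0.28 (adjusted p = 0.0249 with an estimated correlation), and the 366 that had fallen had -0.19 (adjusted p = 0.00923 with an estimated correlation). Across 9602 genes r was 0.55 and rho 0.43. Not every gene named in the first table repeated. Grb10, which had fallen there, was at 0.09 ± 0.14 (SE), and Trim9, among the largest falls there, was at -0.04 ± 0.11. Lists called by camera alone were self-renewal (median -0.18, adjusted p = 0.0191), cell cycle (-0.15, 0.0191), keratins (0.16, 0.0191), matrix genes (0.29, 0.0454) and interferon genes (0.11, 0.0454). With an estimated correlation, a test with little power in this table, their adjusted p lay between 0.774 and 0.875. No member passed the threshold over all probes or adjusted over the list alone. The self-renewal and cell cycle medians were -0.08 and 0.00 without normalization and -0.16 and -0.07 with median scaling, and the keratin median was 0.30 and 0.23. Without any 1 of the 4 medium arrays the line by medium term no longer counts as error, and 1 residual degree of freedom is left. The count then went to 427 without GM replicate 2, 413 without GM replicate 3, 421 without DM replicate 3 and 408 without DM replicate 4. It was 16 with array weights.

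Day 3 was set against day 1 in the infected TS9 cultures of the second table. By limma no probe passed, 843 had an unadjusted p under 0.05, where chance gives 679, and the lowest adjusted p was 0.226. Lists called by camera alone were cholesterol synthesis (median 0.21, adjusted p = 0.000454), the interferon response (0.18, 0.011), p53 targets and inhibitors (0.11, 0.027) and endoderm (0.12, 0.027). Each had an adjusted p = 0.582 with an estimated correlation, where the test has little power in this table. No member passed over all probes, and adjusted over the list alone 2 cholesterol genes and 1 endoderm gene were higher at day 3. Ets2 changed by -0.13 (adjusted p = 0.884). With 1 of the 4 medium arrays left out, which takes the line by medium term out of the error, the count was 671 (GM replicate 2), 655 (GM replicate 3), 681 (DM replicate 3) and 666 (DM replicate 4). It was 15 with array weights and 6 without normalization.

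Infected TS7 cells (AdGFP, day 3, n = 3) were also set against the TS7 culture in GM without virus (day 4, n = 1), a contrast in which virus, day and a single control cannot be told apart. Interferon-induced genes were higher in 10 of 13 members and none passed as lower, with Isg15 at 715.6 ± 108 against 167.2 (log2 difference 2.09 ± 0.15 SE, adjusted p = 2.74e-07), Usp18 (1.85), Oasl2 (1.62) and the tethering protein Bst2 (1.11). Adjusted over the list alone 10 were higher and 2 lower, and the median was 0.50 (camera adjusted p = 3.31e-05, adjusted p = 0.0751 with an estimated correlation). Cholesterol synthesis was higher in 8 of 12, with Fdps (1.05), Dhcr7 (0.83), Sqle (0.70) and Mvd (0.68), and lower in 1. Within the list alone 9 were higher and 1 lower, and the median was 0.58 (camera adjusted p = 0.000634, adjusted p = 0.0751 with an estimated correlation). The endothelial adhesion molecule Pecam1 (2.09, 567.1 ± 86.5 against 131.9), Ctsj (2.08), Pvalb (2.04), Csta2 (2.03), Spred2 (1.35) and Hand1 (1.12) were higher. Uba6 (-1.97), Upp1 (-1.87), Twistnb (-1.76), Sgip1 (-1.76), Phf14 (-1.72), Eomes (-1.64), Mest (-1.60) and Phlda2 (-1.55) were lower. Ets2 differed by 0.00 (adjusted p = 0.995). By limma 8334 of 29915 probes passed, 4877 higher and 3457 lower. The deposited medians of the 5 arrays without AdGFP or AdCreGFP, 4 of them with another adenovirus in their labels, ran from 108.9 to 138.3, above those of the 10 infected arrays, from 92.4 to 108, so that the raw background separates the groups as well. Without normalization 31% of the probes that passed were higher, against 59% with it, and with array weights 14176 passed.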

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

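The tests of wrong labels, of the probe's place in the transcript, of Ets2 among genes of a similar DM change, of the DM score, of the deposited interferon signals and of the interferon level of the lines were chosen only after the result was seen. For the counts over other splits, the test by array brightness and the interferon test in the second table, the prediction was written before the value it concerns was seen, but the last 2 were chosen once their pattern had been found. No group within a table had 4 arrays, so the test used here for a single array far from its group was not run. Fits with array weights and without each array are given with the processing.

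The effect of the virus differed between TS9 and TS7, by a test of the difference itself, for 10 probes in limma and 3 lists in camera, 1 of them also with an estimated correlation. As log2 difference of the effects (TS9 minus TS7), the named genes were Chac1 (1.26), Txnip (-1.14), Dusp4 (1.06), Acta2 (0.99) and Spsb1 (0.83). The probes without a gene name were 106020017 (2.34), 101240110 (1.24), 104590471 (-0.97), 104920152 (-0.92) and 104060685 (0.83). The lists were FGF and ERK response (median 0.19), cell cycle (-0.17) and cholesterol synthesis (-0.14). Without normalization between the arrays the median of the first of these turned to -0.01. Probes 104590471 and 104920152 read only on arrays labelled AdCreGFP at day 3, and whether the lines took up the virus alike was not tested.

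The TS15 array labelled AdCreGFP, whose line has no AdGFP array and which no comparison used, was scored for the first table's virus response. Its score, the median of the 403 genes that had risen less the median of the 366 that had fallen, relative to the TS9 AdGFP arrays, was 0.46. The TS9 arrays labelled AdCreGFP scored 0.45 (day 1) and 0.52 (day 3), the GM arrays -0.10 (TS7) and -0.33 (TS9) and the DM arrays 1.52 and 1.18. The AdGFP arrays lie at 0.01 and -0.01 by construction and give no spread. The score lay above both GM arrays, but these differ between the lines and TS15 has no control, so virus and line were not separated and the difference was not tested.

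Chance is argued against for the count of probes that differed with the virus. Of the 100 splits of the 10 arrays within their lines, 1 gave as many as 1217, the real one, and the highest of the others gave 698. That split placed 0 arrays labelled AdCreGFP on the AdCreGFP side. It kept all of them together on the other side, so it is not free of the virus difference. The median of the other splits was 0. These splits cannot give a share under 1 in 100, so chance is not excluded. For the line, 1 of 60 splits within the viruses gave as many as 4797, the real one, which argues against chance with the same limit. The highest of the others, 3607, exchanges 1 AdGFP array of each line and so keeps 4 of 5 arrays of each side on their line. It also follows the deposited brightness of the arrays, and which of these gives the count was not tested.

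The Ets2 signal was higher on every array labelled AdCreGFP. Single arrays with the wrong virus label are argued against, since 0 of the 10 day 3 arrays lay on the other virus's side for probes chosen without them. A share in the general shift towards the DM profile does not account for its size either: its change of 0.94 lay at percentile 99.8 of 802 genes of a similar DM change, whose median was 0.13 and whose 95th percentile was 0.41. That the probe reads a part of the transcript which the deletion leaves cannot be told apart from a rise of the whole transcript, because neither the probe's place nor the deleted exons are given, and the change of 0.94 decides nothing on it. An exchange of all labels of the viruses, which the test of single arrays cannot see and which would turn every virus direction, stays open and untested, as does a biological rise of the remaining transcript.

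The changes with AdCreGFP ran the way of the changes in DM. Differences between cultures that do not follow the virus are argued against: in the mean DM score of the arrays, 1 of the 100 splits within the lines, the real one, gave a difference as large as 0.135, with 0.102 as the highest of the others. The 4 arrays labelled AdCreGFP scored from 0.060 to 0.078 and the 6 AdGFP arrays from -0.088 to -0.041. Array brightness is argued against as the whole cause, since the correlation across genes was 0.43 in the 5 dimmer and 0.49 in the 5 brighter arrays. A loss of the stem cell state, effects of Cre or of this virus other than on Ets2, and an exchange of all virus labels, which would turn the relation, were not tested and stay open.

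Interferon-induced genes were higher in AdGFP than in GM arrays of the first table. The prediction written before its value was seen came out as the raw background of the GM array would predict. In the second table the list median was -0.14 for infected TS9 cultures against GM. There 3 of the 10 members that had differed in the first table, in TS7, were positive. Against background as the whole cause, the deposited signal of 7 of these 10 members, with Isg15 at 636 to 772 against 210.5 and Bst2 at 8394 to 9375 against 4668, was higher in each AdGFP array than in the GM array. For Mx2, Stat2 and Ifit2, where it was not, background stays open. A response that differs between the lines cannot be told apart, since the list lay at -0.38 in TS9 against TS7 but no table holds infected and uninfected arrays of both lines, and the day of harvest stays open as well.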

How the results depend on the processing

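The settings on array brightness, the lower offset of 16 and the relation of the SB and DM effects were chosen only after the result was seen; the others were set beforehand. The planned floors of 8 and 32 were not run, since the lowest prepared values, 50.79 and 50.73, lie above them. Signal over background limits dim probes, whose fold changes the offset understates.

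For the virus effect (1217) the count was 640 without normalization, 172 without the line, 198 in the 5 brighter arrays and 2141 with brightness as a covariate, and it lay between 662 and 1546 when 1 array was left out. It moved by over 1.5 times without TS9 AdCreGFP replicates 1 (662) and 3 (754), TS9 AdGFP replicates 2 (762) and 3 (765), TS7 AdGFP replicate 2 (747) and TS7 AdCreGFP replicate 2 (800). The share higher was 51% as reported, 73% without normalization and 72% with median scaling. With a replicate block 809 passed, 573 of them shared; the numbers were not shown to pair the cultures (same-numbered arrays correlated at 0.17, 0.03 and 0.24, and with 2 AdCreGFP arrays per line such values mirror each other). For the interaction (10) the count was 4 without normalization, 36 with array weights, 24 with brightness as a covariate and 0 to 12 without 1 array: 0 without TS9 AdCreGFP replicate 3, 1 without TS9 AdCreGFP replicate 1, TS7 AdGFP replicate 2 or TS7 AdCreGFP replicate 1, 2 without TS9 AdGFP replicate 2, 3 without TS9 AdGFP replicate 3 or TS7 AdCreGFP replicate 2 and 5 without TS9 AdGFP replicate 4. Its share higher was 70% as reported, 25% without normalization and 45% with median scaling. The line count (4797) was 1587 and 699 in the 5 dimmer and 5 brighter arrays, each 4 arrays of 1 line against a single array of the other, and its share higher went from 55% to 22% without normalization and 41% with median scaling.

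DM against GM of the second table (4014) gave 1789 from 4 arrays without the line. The SB count (2960) lay between 1767 and 1926 without 1 array (DM replicate 2 1926, DM replicate 1 1863, SB replicate 1 1767, SB replicate 2 1822), and its share higher was 68% with median scaling. In the second table the limma count of 0 for the virus became 16 with array weights and 0 to 427 without 1 array (GM replicate 2 427, GM replicate 3 413, DM replicate 3 421, DM replicate 4 408), with 590 at an unadjusted p under 0.05. That of 0 for the day became 6 without normalization, 15 with array weights and 0 to 681 without 1 array (GM replicate 2 671, GM replicate 3 655, DM replicate 3 681, DM replicate 4 666), with 843 at an unadjusted p under 0.05. These counts rise without a medium array because the line by medium term then leaves the error. AdGFP against GM gave 14176 with array weights, and its share higher went from 59% to 31% without normalization. Without normalization the median of all probes shifted by -0.11 for the interaction and -0.15 for AdGFP against GM. For the other settings here the cause was not tested.

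Lists called by camera, then with an estimated correlation, went from 9 to 2 for the virus, 3 to 1 for the interaction, 4 to 0 for the line, 8 to 0 and 10 to 5 for DM in the second and first table, 5 to 0 and 4 to 0 for virus and day in the second table, and 2 to 0 for AdGFP against GM. In the second table the estimated correlation leaves a test on 2 residual degrees of freedom, so its counts of 0 there decide little. Fry, which asks whether a list moves at all, called 15 for the line, 18 for DM in the first table, 13 for SB, 0 for virus and day in the second table, and 8 for AdGFP against GM. The correlation of virus and DM effects (0.53) was 0.46 with DM of the first table and 0.47 to 0.56 without 1 array. That of DM between tables (0.91) was 0.90 with gene means and 0.896 to 0.902 without 1 array, that of the virus between tables (0.55) 0.48 to 0.63, and that of SB and DM (-0.50) -0.484 to -0.477. Of 7488 values of named genes under these settings, 6968 kept their direction and side of the threshold, 512 fell short of it, 7 passed it newly and 1 reversed: the line difference of Egln3 was 0.00929 in the 5 dimmer arrays, against -0.31. Values fell short most often for the virus effect without the line (45), then in the 5 brighter arrays for the line difference (33) and the virus effect (32). The cause was not tested.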

Other observations

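The virus-only probes were chosen only after the result was seen, and the infected against GM contrast of the second table only after the interferon pattern of the first.

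In DM of the first table, changes not described so far included rises of Peg10 (2.63), an imprinted gene derived from a retrotransposon, and of Id3 (2.10), an inhibitor of helix-loop-helix factors. The endocytic adaptor Dab2 (-1.98) and Srebf2 (-1.62), a regulator of sterol genes, fell. Of the p53 targets and cell cycle inhibitors 6 of 15 rose and 1 fell, with Sesn1 (1.16), Cdkn1a (1.11) and Cdkn2b (0.86) among the rises, in a list that was not called (camera adjusted p = 0.0614).

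Between the lines, members of the FGF and ERK list went both ways, with Fosl1 (0.84) and Phlda1 (0.54) higher in TS9 and Fos (-0.58) lower, and the list was not called (camera adjusted p = 0.915). Inhibitors of the cell cycle also parted, with Cdkn1a (0.57) higher and Cdkn2a (-0.54) lower in TS9 (camera adjusted p = 0.838). Among matrix genes the gelatinase Mmp9 (0.92) was higher and Timp3 (-0.71) and Mmp11 (-0.62) were lower (camera adjusted p = 0.710).

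Some probes without a gene name read by at least 10-fold in cultures with a given virus only. Probe 104540411 lay between 6732 and 11077 on the 4 arrays labelled AdCreGFP and between 56.2 and 76.5 on the 6 AdGFP arrays of the first table, probe 104590471 between 1496 and 3077 against 80.8 to 91.7, and probe 104920152 between 2223 and 4391 against 80.6 to 82.8. Probe 105130600 read 2032 to 3715 on AdGFP arrays and 69.8 to 86.8 on those labelled AdCreGFP. Probe 6420138 read 3152 to 4673 on infected arrays and 153.6 to 183.7 on the other 5, 4 of which mention another adenovirus in their labels, so its absence there does not show that these cultures were without virus. By line, the mean of each of these probes on the arrays where it read was lower in TS9 than in TS7. Probe 104540411 read 6985 against 10937, and probe 105130600 read 2421 against 3393. Probe 6420138 read 3629 against 4028 on AdGFP arrays and 3237 against 4614 on those labelled AdCreGFP. On AdGFP arrays its ranges overlapped, at 3152 to 4468 in TS9 and 3447 to 4491 in TS7. None of these probes is in the second table, and what they read is not given.

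In the second table, infected TS9 cultures differed from uninfected GM cultures at 429 probes by limma, 261 higher and 168 lower. That table holds no infected TS7 culture. The contrast is the infection term of the additive fit, so its p-values measure departures from that fit and not the spread between replicate cultures. The only TS9 culture in GM there has no day in its labels, so virus and day cannot be told apart. Cell cycle and cholesterol synthesis genes had medians of -0.32 and -0.32 (camera adjusted p = 0.0139 each), although 1 of 21 cell cycle genes passed, as higher, and 1 of 12 cholesterol genes, as lower. The medians were -0.27 for hypoxia and glycolysis genes (0.0287, none of 13 past the threshold) and -0.24 for imprinted genes (0.047, 1 of 12 lower). Each of these 4 lists had an adjusted p = 0.75 with an estimated correlation, a test with little power in this table. For cholesterol synthesis this is opposite to the median of 0.58 in AdGFP against GM of the first table.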
